A study of Xenopus laevis with 8 samples.

How the data were processed

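Gene expression was measured on 8 Affymetrix arrays, 1 per sample, in foregut endoderm explants of Xenopus laevis. Per the labels, explants were taken at stage 15 and cultured to stage 23, either intact with their mesoderm or as endoderm alone. Per the labels' protocols, the endoderm of the intact explants was then isolated, both kinds of endoderm were frozen, total RNA was extracted with Trizol, and biotinylated cRNA was made by the standard Affymetrix protocol. Each condition has 4 samples, labelled set 1 to set 4. The labels do not say whether the sets are separate clutches, animals, dissection days or array batches. The p-values of single probe sets measure the spread between samples or, with the set as a block, that of the differences within sets. Camera, the main test of gene lists, compares a list with other genes.

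The values in the deposited tables are RMA expression values, per the labels, and each is an intensity per probe set on the linear scale. RMA corrects for background, normalizes probe values by quantiles and summarises them per probe set. The RMA version and software are not given in the sources used here. Per the file headers, which name 2 data sets, the values may have been normalized or exported together with those of another data set, which is not in the series. The deposited annotated table and the deposited series matrix were identical in 124888 of 124888 cells, so the planned use of the series matrix in place of the annotated table changed nothing. No counts lie behind these values, and the number of arrays limits their precision. Log2 was taken of every value before any test.

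The table held 15611 probe sets, of which 120 control probe sets were left out of the tests and 15491 were tested. Gene names came from the name column of the deposited table, matched to a RefSeq gene table by symbol for 2022 probe sets, by gene ID for 2078, by synonym for 1289 and by hand for 5, and kept as written in the file for 406. A total of 5800 probe sets had a gene name, for 3941 distinct genes, and 9691 had none or only a clone, LOC or MGC name. No genome came with the arrays, so no positions are given. Among the genes that were to be named always, foxa2 could not be matched to a probe set.

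Endoderm cultured with mesoderm was compared with endoderm cultured alone by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no other term in the model and Benjamini-Hochberg adjustment over the 15491 probe sets. A probe set was called at an adjusted p under 0.05. Whether the set numbers pair the samples was checked once, from the correlation of the paired arrays' deviations from the mean of their condition. It was 0.84, 0.85, 0.69 and 0.32 in sets 1 to 4, above the 0.1 taken as the lowest value for a pair. The fit with the set as a block, planned as an alternative, is therefore given beside the fit without it, and its results are called within sets. Log2 differences are with mesoderm minus alone, and the ± after one is the SD of the 4 differences within sets unless another is named.

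There were 23 gene lists, 15 of pathways and of endoderm regions and 8 of markers of other cell types that a dissected explant could hold. They were tested with camera in limma at a preset correlation of 0.01, with 1 probe set per gene (the brightest), 3941 genes, and adjustment over the 22 lists with at least 5 measured members. The FGF and ERK response list had 4 measured members and was not tested. Beside it, camera was run with an estimated correlation, and fry was run. The PValue of fry tests whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction; neither compares the list with other genes. Members that passed were counted with adjustment over all probe sets and adjusted over the list alone.

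The genes named were chosen by a rule: the 12 largest rises and 12 largest falls among called probe sets whose 4 arrays of each condition do not overlap, filled up by lowest p to 6 each way when fewer pass. Up to 3 called members and the 2 brightest members of each tested list were added, and 15 genes of the foregut and its neighbours were to be named always. Because the fit without a set block called nothing, the rule was also applied to the fit within sets, requiring the same direction in all 4 sets. A few further genes are named where a count is small, and these were chosen after their values were seen. The values of 2 genes that the rule took are not reported here.

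The tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Those alternatives were the set as a fixed block and as a random effect (duplicateCorrelation), a trended and robust variance, array weights, quantile normalization again, median centring, filters on dim probe sets, 1 mean value per gene, thresholds of 0.01 and 0.1, a fold of at least 2, non-overlap of the groups, and leaving out each array and each set. Chosen after seeing the data were cyclic loess normalization, the same alternatives within sets, list tests within sets without each set, 2 further gene lists, and a test of the first of these without members already seen. The 2 further lists, of myeloid cells and of targets of FoxO factors and the glucocorticoid receptor, were tested for the closing section.

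The fits were tested on simulated data of 15491 probe sets with the set structure of these arrays, in which 100 were changed by 1 and 100 others by 2 on the log2 scale. Without the set block, 23 of the former and 89 of the latter were recovered, with 0 false calls. With the block, 72 and 97 were recovered, with 8 false calls. In camera, a list of 16 genes shifted by 0.6 had an adjusted p of 5.9e-20, and 0 of 21 other lists were called. The noise was drawn independently for each gene and equally wide in every set. The simulation therefore does not show how often lists are called falsely where genes are correlated or 1 set is noisier. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.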

Results

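RNA of Xenopus laevis foregut endoderm was measured at stage 23, in 4 samples cultured with mesoderm until then and 4 cultured as endoderm alone from stage 15 on. Array medians, as the deposited linear intensities, ran from 127.5 to 131.2. The arrays grouped by set number rather than by culture condition. Of the 8 arrays, 7 correlated best with the array of the other condition in the same set (Pearson r over probe sets, which are not independent replicates). The exception was an array of set 4. The correlations within sets 1 to 4 were 0.992, 0.99, 0.987 and 0.97, and the lowest between any 2 arrays was 0.942. Differences between sets held 76.4% of the sum of squares and differences between conditions 8.98%. On the fourth principal component, with 9.07% of the variance, all 4 arrays with mesoderm lay above 0 and all 4 alone below 0. The spread of the differences within a set was widest in set 4, with an SD of 0.528 over probe sets against 0.25, 0.312 and 0.331 in sets 1 to 3.

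**Figure D1:**
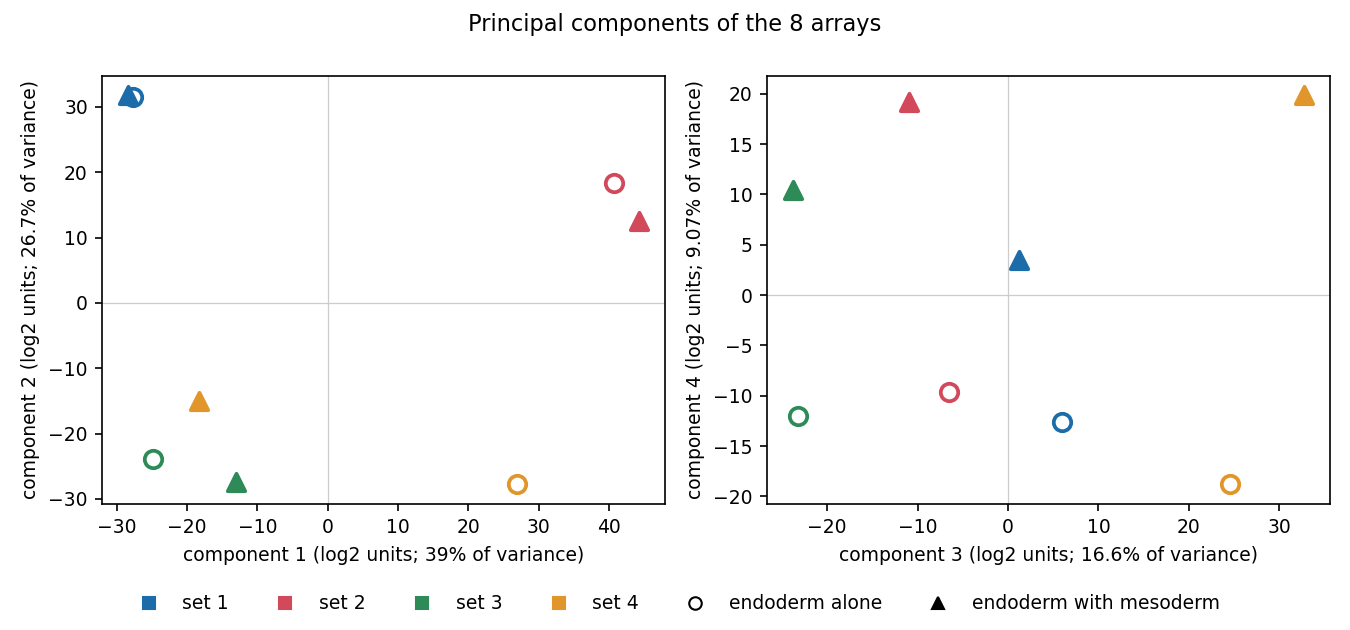
Scores of the 8 arrays on the first 4 principal components of the log2 intensities, in log2 units with the share of variance of each component, colours for the set and symbols for the culture condition. On the first component (39.0%) the arrays of set 4 stand apart at 26.96 alone and -18.24 with mesoderm, and on the fourth (9.07%) all 4 arrays with mesoderm lie above 0 and all 4 alone below 0.

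The comparison asked which transcripts of the foregut endoderm differed when mesoderm was present during culture. Endoderm with mesoderm was isolated at the end of culture and endoderm alone at its start. The time of isolation therefore cannot be told apart from the presence of mesoderm for any gene below. Within sets, the most strongly raised named gene was szl, or sizzled, a secreted inhibitor of tolloid proteases and a target of BMP signalling, at 5.17-fold the level of endoderm alone. Egr1, an immediate early transcription factor, stood 3.44-fold higher, and several genes known from white blood cells rose with it, among them lcp1, the actin-bundling protein of leukocytes, 3.23-fold and prtn3, a neutrophil granule protease whose level alone lay at background in 2 of the 4 sets. After cyclic loess egr1, lcp1 and prtn3 no longer passed (adjusted p 0.0651, 0.0824 and 0.103). The largest fall was that of sgk1, the serum- and glucocorticoid-regulated kinase, to a level 10.98-fold lower with mesoderm. Ambp, the precursor of a plasma protein of the liver, was 3.13-fold lower and sox9, a transcription factor, 2.01-fold lower.

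These calls came from limma with the set as a block, which gave 40 probe sets higher and 20 lower with mesoderm. All 60 went the same way in all 4 sets. Without the block limma called 0 higher and 0 lower, and 203 and 181 had an unadjusted p under 0.05. The set as a random effect in limma gave 56 higher and 26 lower. Groups of 4 that did not overlap were seen for 160 probe sets higher and 133 lower, against 221 in each direction expected by chance if all 8 arrays were exchangeable. The sets pair the arrays, which lowers the number chance gives, so these counts do not show fewer differences than chance. The calls within sets ranged in size from a log2 of 0.71 to 2.86 higher and from 0.707 to 3.46 lower, and 31 and 12 of them were at least 2-fold. Among them 17 probe sets higher, for 15 genes, and 10 lower, for 10 genes, carried a gene name. The number of calls within sets changed with the set that was left out. With set 1 left out 2 probe sets passed, of sgk1 and szl. With set 2 left out limma called 0, and 397 higher and 455 lower had an unadjusted p under 0.05. With set 3 left out 12 passed, 10 of them among the 60, and with set 4 left out 275 passed, all of the 60 among them.

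Szl had a mean log2 level of 7.58 ± 1.34 alone and 9.95 ± 1.10 with mesoderm (SD over 4 arrays), a difference of 2.37 ± 0.69 with an adjusted p of 0.0166. Without the set block its adjusted p was 1.00. A homeobox gene that acts downstream of BMP, ventx2.2 (xom-A in the file), rose by 1.18 ± 0.47 (adjusted p 0.049). Its log2 levels alone in sets 2 and 4, 4.45 and 3.60, stood beside 4.31 and 4.46 for the negative controls, so its size of change is uncertain. Egr1 rose by 1.78 ± 0.71 (adjusted p 0.0404). The ERK-activated kinase rps6ka1 rose by 1.58 ± 0.73 (adjusted p 0.049), and dusp1, a phosphatase that inactivates MAP kinases, by 0.71 ± 0.11 (adjusted p 0.049), while a second dusp1 probe set stood at 0.34. After cyclic loess szl passed (adjusted p 0.0421), but ventx2.2, egr1, rps6ka1 and dusp1 did not (0.0607, 0.0651, 0.0655 and 0.0824).

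Of the genes known from blood cells, prtn3 rose by 2.06 ± 0.98 and lcp1 by 1.69 ± 0.76, each with an adjusted p of 0.049. The log2 level of prtn3 alone was 4.75 in set 1 and 4.74 in set 3, beside 4.65 and 4.75 for the negative controls, so its size of change is uncertain. Fcrg rose by 1.32 ± 0.50 (adjusted p 0.0415), and csf2rb, the shared subunit of receptors for myeloid growth factors, by 1.06 ± 0.22 (adjusted p 0.0292). Without the set block csf2rb had an adjusted p of 0.171. The myeloperoxidase gene mpo stood 2.08 ± 1.52 higher and did not pass (adjusted p 0.174). Its difference was 0.18 in set 4, and its adjusted p within sets was 0.00170 without that set. Without set 1, 2 or 3 that p was 0.48, 0.63 and 0.29. Also raised within sets were a probe set listed under mig30 (1.58, 1 of 7 under that name, its identity in doubt), the RNA helicase gene ddx39a (1.22), neurl-A (0.91) and nipa2 (0.88), with adjusted p from 0.0292 to 0.049. After cyclic loess csf2rb, ddx39a and neurl-A passed, but prtn3, lcp1, fcrg, mig30, nipa2 and syne1 did not (adjusted p 0.103, 0.0824, 0.0655, 0.107, 0.0824 and 0.0974). The differences of the latter were then 2.05, 1.70, 1.33, 1.56, 0.84 and 0.76. Second probe sets of ddx39a and nipa2 stood at -0.20 and 0.12. Syne1, a protein of the nuclear envelope, was called at 0.80, between log2 levels of 3.56 and 4.36 that lie at or below those of the negative controls.

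Sgk1 went from a mean log2 level of 10.92 ± 0.33 alone to 7.46 ± 0.91 with mesoderm (SD over 4 arrays), a difference of -3.46 ± 0.67. Its adjusted p was 0.00532 within sets and 0.145 without the block, and it was the 1 probe set called without the block when the array with mesoderm of set 4 was left out. Ambp differed by -1.64 ± 0.33 (adjusted p 0.0159), with a second probe set at -0.03. The transporter gene slc16a6, of the monocarboxylate transporter family, differed by -1.59 ± 0.37 (adjusted p 0.0166). Sox9 went from a mean log2 level of 9.98 ± 0.64 to 8.97 ± 0.53 (SD over 4 arrays; adjusted p 0.0415), and ripply2, a corepressor of somite segmentation, differed by -1.26 ± 0.47 (adjusted p 0.0415; matched from the older name bowline, with its identity in doubt, since another probe set of this gene stood at 0.10). Also lower were the metallothionein gene mt4 (mt-A in the file, so which metallothionein gene it is stays in doubt) by -0.98 ± 0.10, the sestrin sesn1 by -0.89 ± 0.23, and pdk4, which inhibits pyruvate dehydrogenase, by -0.86 ± 0.12. Their adjusted p were 0.0229, 0.0415 and 0.0348. The lysosomal membrane protein gene scarb2 differed by -1.02 (adjusted p 0.0479; a second probe set stood at -0.02) and nfyb, a subunit of a CCAAT-binding factor, by -0.85 (adjusted p 0.0407). After cyclic loess sgk1, ambp, slc16a6, sox9, mt4 and sesn1 passed, but ripply2, pdk4, scarb2 and nfyb did not (adjusted p 0.063, 0.0627, 0.0702 and 0.063).

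Without the set block, the genes with the lowest p were csf2rb, fcrg, kctd12, fgl2, syne1 and mig30 on the higher side and sgk1, slc16a6, pdk4, gadd45g, scarb2 and arl4a on the lower, and none of these 12 passed. Of them kctd12 (1.53), fgl2 (1.70), gadd45g (-1.09) and arl4a (-0.59) did not pass within sets either, with adjusted p of 0.0621, 0.0711, 0.172 and 0.103. Without set 4, which had the widest differences, kctd12, fgl2 and arl4a passed within sets, but they did not without set 1, 2 or 3.

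**Figure D2:**
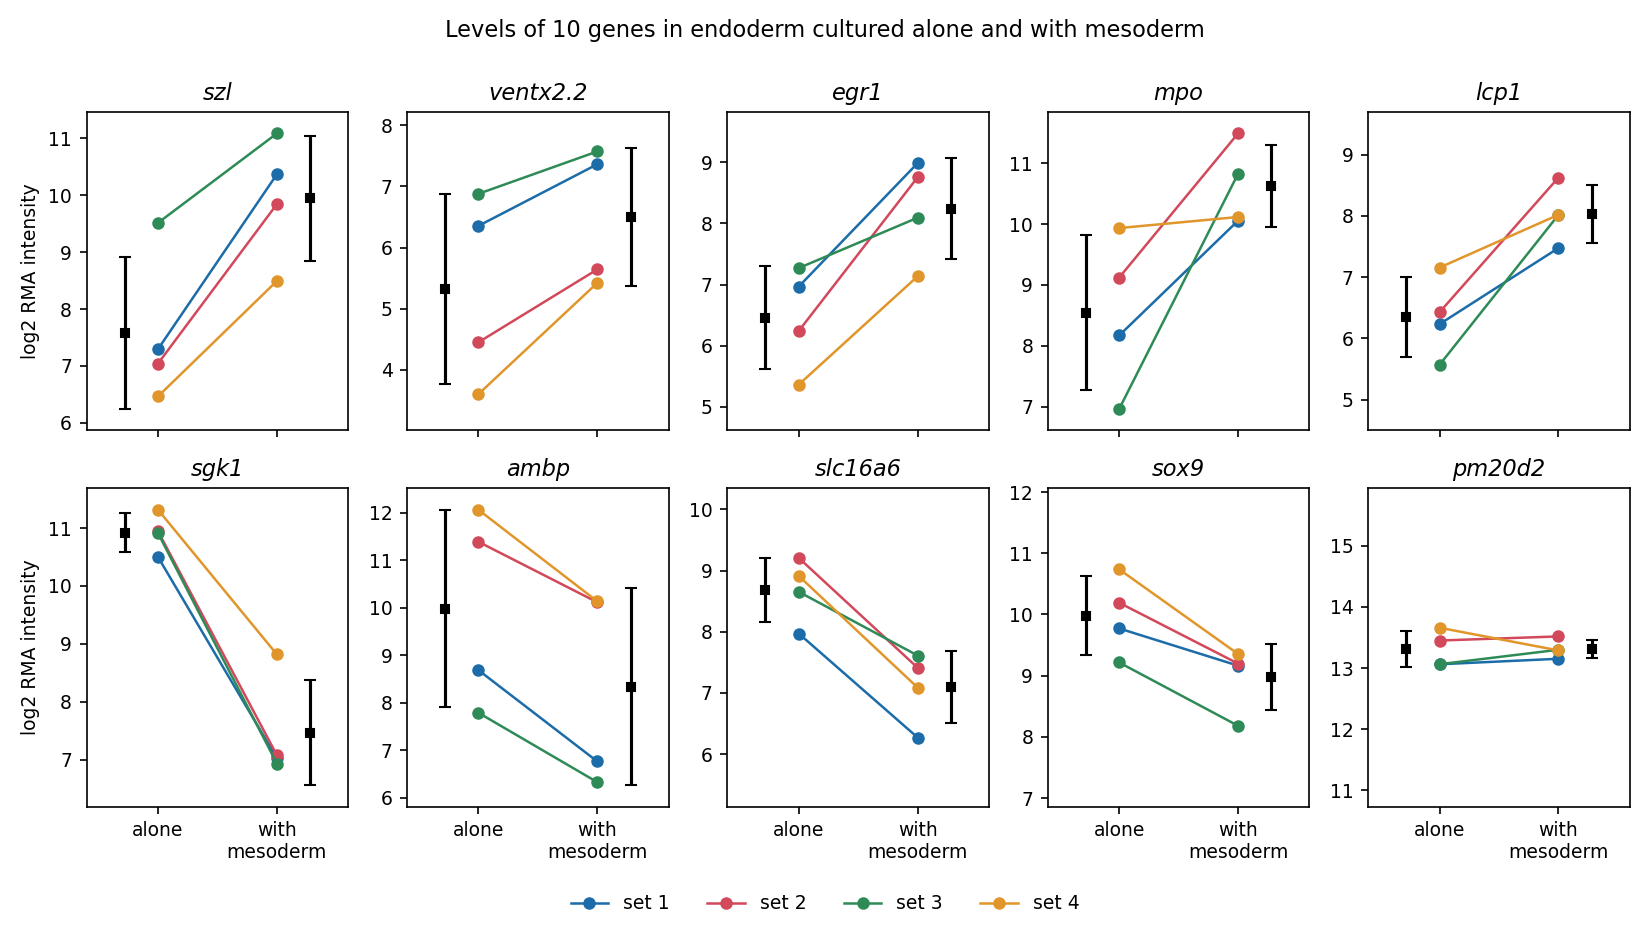
Log2 RMA intensity of 10 genes in endoderm cultured alone and with mesoderm, 1 point per array, with a coloured line joining the 2 arrays of each set and black squares and bars for the mean and SD of 4 arrays. Szl, ventx2.2, egr1 and lcp1 rose within sets and sgk1, ambp, slc16a6 and sox9 fell, each in all 4 sets, while mpo (2.08) and pm20d2 (0.01) did not pass.

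The second comparison asked which groups of genes shifted together. The BMP response list, of targets and ligands of bone morphogenetic protein signalling, was higher with mesoderm, with a median log2 difference of 0.28 and 13 of 16 members above 0 (adjusted p 0.656 with an estimated correlation, so the call was lost). Also higher in the test were lists of other regions and tissues: blood and vascular precursors, cardiac and lateral plate mesoderm, and posterior endoderm and hindgut, with medians of 0.14, 0.13 and 0.17. These calls too were lost with an estimated correlation (adjusted p 0.656, 0.682 and 0.656). The genes that mark the foregut and the endoderm as a whole did not shift as lists, and hhex, a homeobox gene of the early liver and foregut, differed by 0.04 ± 0.19. The log2 level of hhex alone, 5.29, lay close to the negative controls, so a lack of change cannot be read from this. Camera called these 4 of the 22 lists as higher and 0 as lower, both with and without the set block; at an unadjusted p under 0.05 it had 6 higher and 1 lower without the block and 8 and 1 with it. The one-way test of fry and camera with an estimated correlation called 0 lists either way. At an unadjusted p under 0.05 fry had 0 higher and 1 lower without the block, and 2 and 0 with it. Camera with an estimated correlation had 0 higher and 0 lower without the block, and 1 and 0 with it. The mixed test of fry called 5 lists with the block: stress (adjusted p 0.000299), BMP response (0.00847), BMP antagonists and proteases (0.0125), foregut (0.0188) and apoptosis (0.0188), and without it the stress list. In each of these but stress, 1 member was called over all probe sets within sets: szl in both BMP lists, ambp in foregut and sesn1 in apoptosis. The mixed test does not show whether a list changed as a group or through such single genes.

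**Figure D3:**
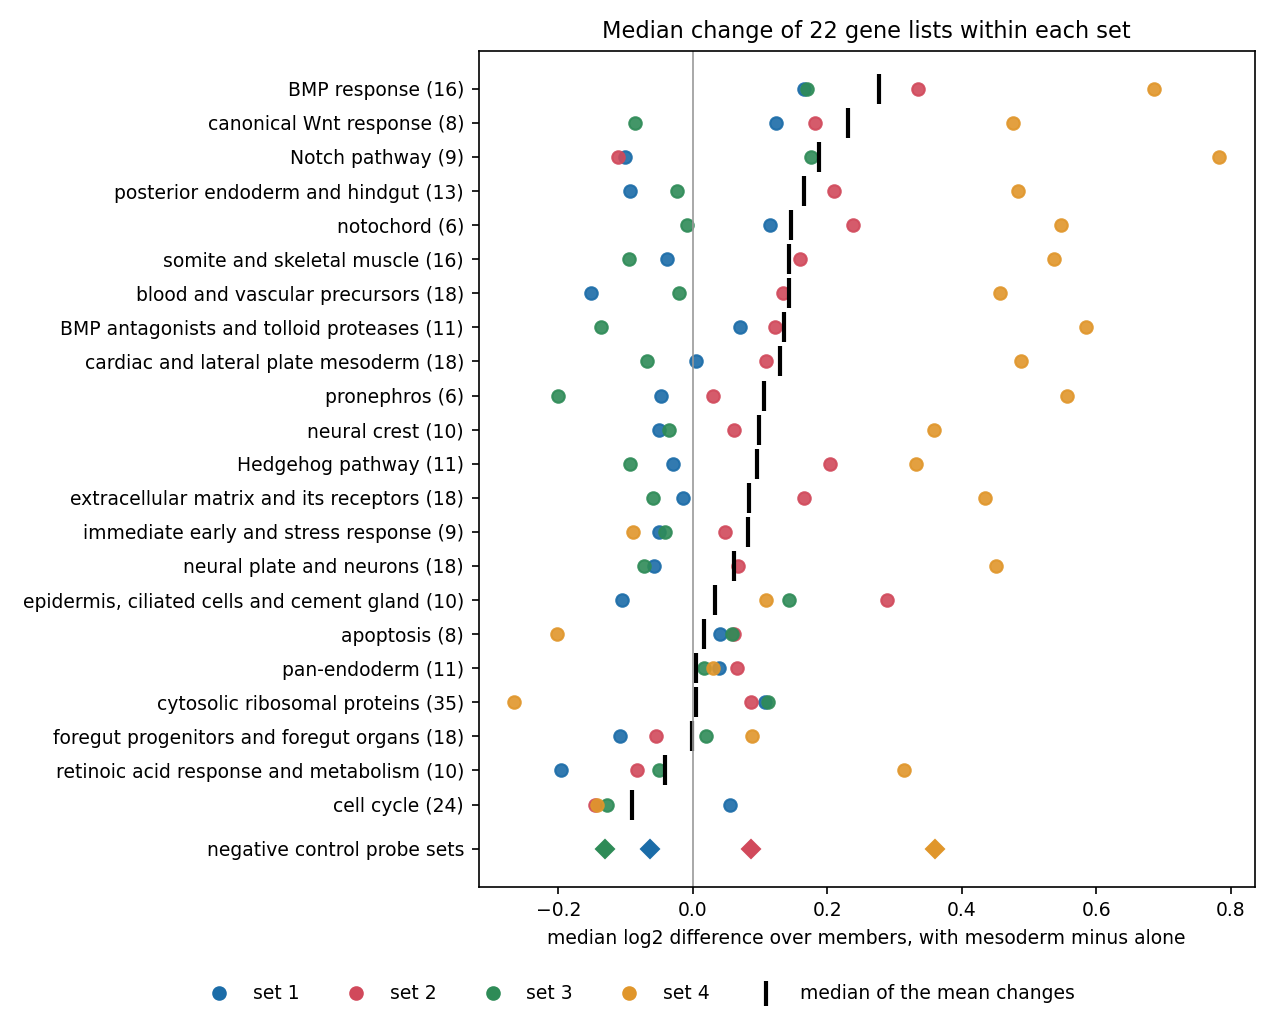
Median log2 difference (with mesoderm minus alone) of the members of each gene list, 1 point per set and a bar for the median of the members' mean differences, with 50 negative control probe sets (diamonds) for comparison. The BMP response list lay above 0 in all 4 sets, at 0.165, 0.335, 0.169 and 0.685, and it and most lists of other tissues had their highest median in set 4, like the negative controls (0.36).

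In the BMP response list the adjusted p was 0.0139 without and 0.000156 with the set block. With an estimated correlation the adjusted p was 0.656 without and 0.374 with the block, so no call held. In fry the adjusted p was 0.823 and 0.198. Within sets szl was the 1 of 16 members called over all probe sets, and 5 rose when adjusted over the list alone: szl, the ventral homeobox genes ventx1.1 (0.64 ± 0.20) and ventx2.1 (0.75 ± 0.55), the homeobox gene msx2 (0.58 ± 0.27) and the feedback inhibitor smad7 (0.62 ± 0.56). Msx2 and smad7 were named after their values were seen. The brightest members, the inhibitor of DNA binding genes id2 and id3, which BMP signalling also induces, differed by -0.20 ± 0.08 and -0.18 ± 0.12. Without the block the list was not called when the array with mesoderm of set 1 (adjusted p 0.102), that of set 3 (0.240), the array alone of set 4 (0.868) or both of set 4 (0.107) were left out. The list medians in sets 1 to 4 were 0.165, 0.335, 0.169 and 0.685, highest in set 4, then set 2, like those of the 50 negative control probe sets (-0.063, 0.087, -0.13 and 0.36). Within sets it was called without any 1 set, with an adjusted p of 0.00177 without set 4.

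The blood and vascular list had an adjusted p of 0.00373 without and 0.00372 with the block, and 17 of 18 members lay above 0, although no member passed over all probe sets in limma, where 3 were higher at an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.656 and 0.692, and the call was lost. Adjusted over the list alone, lmo2, a cofactor of blood cell transcription factors (0.71 ± 0.36), and mpo rose within sets. The brightest members, cebpa, a myeloid transcription factor, and mpo, stood at 0.37 and 2.08, and the red cell genes hba1 and gata1, named after their values were seen, at 0.03 and 0.13, the former at background. The list medians in sets 1 to 4 were -0.151, 0.134, -0.0211 and 0.457. The 50 negative control probe sets differed in the same direction in each set, with medians of -0.063, 0.087, -0.13 and 0.36. Without the array with mesoderm of set 3 it was 0.0712 and without set 4 it was 0.107, or 0.417 within sets. After cyclic loess the adjusted p within sets was 0.0561.

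The cardiac and lateral plate list had an adjusted p of 0.0289 without and 0.0207 with the block, with 16 of 18 members above 0 and 0 called in limma over all probe sets or adjusted over the list alone (1 higher at an unadjusted p under 0.05). With an estimated correlation the adjusted p was 0.682 and 0.692, and the call was lost. Its brightest members, the cardiac transcription factors nkx2-5 and tbx2, stood at 0.47 ± 0.74 and 0.55 ± 0.32. Hand1 and foxf1, transcription factors of lateral plate mesoderm, differed by -0.03 ± 0.26 and 0.00 ± 0.34, but the log2 level of foxf1 was 4.75 alone, at background, so no change could be measured. The posterior endoderm list had an adjusted p of 0.0425 and 0.0207, with 11 of 13 members above 0; none was called over all probe sets (3 higher and 1 lower at an unadjusted p under 0.05) and 2, ventx1.1 and ventx2.1, adjusted over the list alone. With an estimated correlation its adjusted p was 0.656 and 0.692, and the call was lost. Both genes belong to the BMP response list as well. Cdx2, a transcription factor of the hindgut, stood at 0.49 ± 0.45. The medians of the 13 posterior genes in sets 1 to 4 were -0.093, 0.21, -0.0229 and 0.483, and those of the cardiac list 0.00542, 0.109, -0.0677 and 0.488, again highest in set 4, then set 2, like those of the negative controls.

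Nor did the cardiac and the posterior call hold after quantile normalization (adjusted p 0.121 and 0.126) or cyclic loess (0.126 and 0.127). Without set 4 the adjusted p within sets were 0.86 and 0.417, and without the block 0.809 and 0.491. Without the block the cardiac call was also lost without the arrays with mesoderm of sets 1 (0.0779), 3 (0.0712) or 4 (0.535) and the arrays alone of sets 2 (0.482) or 4 (0.245). The posterior call was lost without the same arrays, at 0.0784, 0.231, 0.276, 0.515 and 0.243, and without set 2 at 0.0573. The number of lists called higher without the block became 7 without the array alone of set 1 or of set 3, 2 without the array with mesoderm of set 1 or of set 4, 1 without the array alone of set 4, 0 without the array with mesoderm of set 3 or without set 4, and 9 without set 3.

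**Figure D4:**
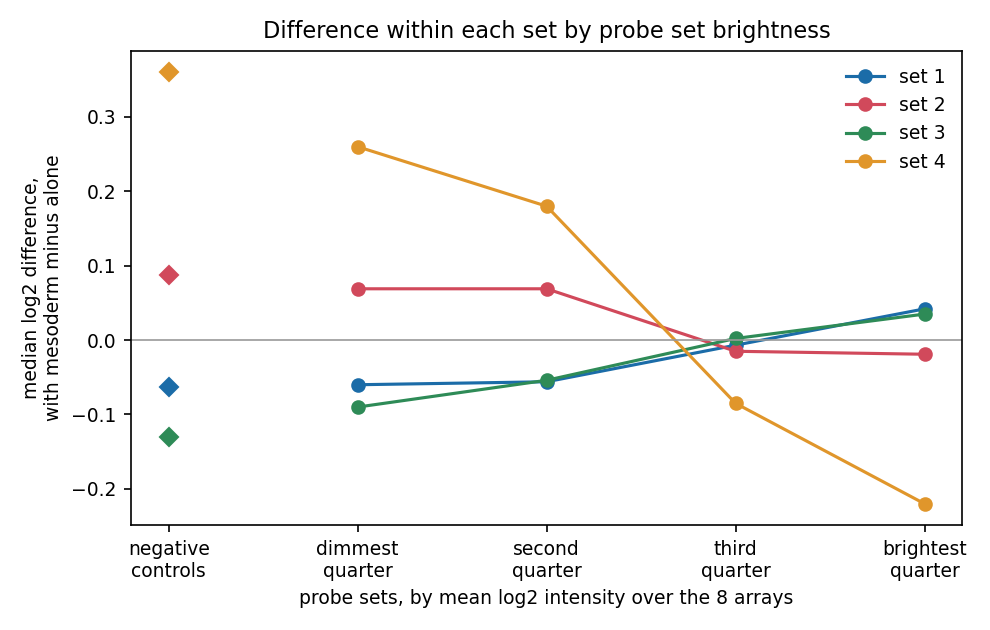
Median log2 difference within each set for probe sets grouped by mean intensity, from the dimmest 3873 to the brightest 3873, and for 50 negative control probe sets. In set 4 the dimmest stood at 0.26, the controls at 0.36 and the brightest at -0.22, while sets 1 to 3 lay between -0.13 and 0.087.

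In the foregut list (18 members) 9 lay above 0 and 9 below, and its adjusted p was 0.841. Ambp was the 1 member called over all probe sets and the 1 adjusted over the list alone. The brightest members, foxa1, a transcription factor of endoderm, and gata6, differed by -0.01 ± 0.16 and -0.26 ± 0.25. The liver, thyroid and lung factors nr1h5 and nkx2-1 stood at 0.14 ± 0.31 and 0.14 ± 0.39, and the secreted Wnt inhibitors sfrp5 and cer1 at -0.05 ± 0.07 and -0.18 ± 0.19. The log2 levels of hhex (5.29 alone), cer1 (5.39 alone) and nr1h5 (4.80 alone) lie close to those of the negative controls, whose array means ran from 4.31 to 4.81. These genes were therefore measured at about background. Nkx2-1 was little higher, at 5.60 alone. The pan-endoderm list (11 members) had an adjusted p of 0.896, 6 members above 0 and 0 called in limma, over all probe sets or adjusted over the list alone (1 lower at an unadjusted p under 0.05). Its brightest member, pm20d2 (darmin in the file), had a log2 level of 13.31 in both conditions. The endoderm factors sox17a and sox17b.1 stood at -0.53 ± 0.65 and 0.02 ± 0.74, and sox17a was low in the array with mesoderm of set 4.

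The lists of other signalling pathways did not pass. The adjusted p was 0.144 for BMP antagonists and tolloid proteases, 0.114 for the canonical Wnt response, 0.987 for retinoic acid, 0.374 for Hedgehog, 0.141 for Notch and 0.238 for extracellular matrix and its receptors. Among BMP antagonists and proteases, szl, noggin (nog, 0.52) and twsg1 (0.61) rose within sets and the tolloid-like protease gene tll1 (-0.59 ± 0.27) fell, each adjusted over the list alone; of these szl was called over all probe sets. Nog and twsg1 were named after their values were seen, and the log2 level of nog alone, 4.48, was at background. Fzd7, a Wnt receptor (-0.32), dact1 (-0.03), rarg, a retinoic acid receptor (-0.18), shh (0.10), smo (-0.36), hes4 (0.78) and hey1 (0.90) were among the brightest of their lists and none was called. The matrix protein fibronectin, fn1, stood at -0.01 ± 0.17 and its receptor subunit itgb1 at -0.01 ± 0.15. Of the 4 measured genes of the FGF and ERK response egr1 was called, over all probe sets and adjusted over the list alone, and the other 3 (named etv1, etv4 and spry2) lay between 0.00 and 0.27.

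Stress genes moved in both directions, and the time of isolation also differed between the 2 conditions. Of 9 measured members of the immediate early and stress list, egr1 and dusp1 rose and sgk1 fell within sets over all probe sets. Adjusted over the list alone, 2 rose and 3 fell, the further ones being gadd45g and the matricellular gene ccn2 (-0.71 ± 0.30, named after its value was seen). Without the block the list had an adjusted p of 0.306 in camera and 0.823 in the one-way test of fry. The mixed p of fry, also without the block, was 0.000935 after adjustment. The list had a median of 0.08, a mean of -0.26 and a camera test that pointed down. Its brightest members were sgk1 and the chaperone hspa5 (0.25). In the apoptosis list (adjusted p 0.875) sesn1 was the 1 of 8 members called, over all probe sets and adjusted over the list alone. That list had a median of 0.02, a mean of -0.06 and a test that pointed up without and down with the block. The cell cycle list had 18 of 24 members below 0, a median of -0.09 and an adjusted p of 0.0782, with pcna at 0.31 and rrm2.2 at 0.12. The 35 ribosomal protein genes had a median of 0.00 and an adjusted p of 0.841, with rps13 at 0.04 and rps27 at -0.08; without set 4 they were called as higher within sets (adjusted p 0.00115).

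Markers of further cell types did not shift as lists. The adjusted p was 0.0677 for somite and skeletal muscle, 0.238 for notochord, 0.206 for neural plate and neurons, 0.841 for neural crest, 0.372 for epidermis and 0.325 for pronephros. Within sets sox9 was the 1 crest gene called over all probe sets, and sox9 and ets1 (-0.60 ± 0.38), another transcription factor of the crest, fell when adjusted over the list alone. Other probe sets of ets1 stood at -0.38 and 0.48. The crest list had a median of 0.10, a mean of -0.07 and a test that pointed up without and down with the block. Nog was the 1 notochord gene called when adjusted over the list alone. Pax3 (-0.54), atp2a1 (0.06), foxa4 (-0.05), sox11 (-0.07), sox2 (0.28), krt70 (-0.02), pitx1 (0.15), osr1 (0.04) and irx3 (0.32), bright members of these lists, were not called. The pax3 probe set used had a log2 level of 12.42 alone, and others under that name ran from 4.22 to 11.48. That of atp2a1 had 10.11 alone and a second probe set 6.24. The identity of these 2 genes is therefore in doubt. In set 4 the medians of the muscle, notochord, neural and pronephric lists were 0.537, 0.547, 0.451 and 0.557, beside 0.36 for the negative controls. The actin 3' minus 5' log2 value, a sign of RNA or labelling quality, went from -1.32 alone to 1.00 with mesoderm in set 4. It went from 2.43 to 2.32, from -0.01 to -0.61 and from 0.64 to -0.58 in sets 1 to 3. The GAPDH 3' minus 5' value went from 3.26 to 3.31 in set 4, and from 2.29 to 2.42, 3.05 to 3.06 and 3.82 to 3.35 in sets 1 to 3.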

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

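In this part the tests of chance by splitting the samples were planned, and those of a raised background on 1 array were chosen after the result was seen. Among 262 groups of 4 values (levels in 1 condition, or differences within the 4 sets), 15 held a value far from the other 3, and 8 of the 15 were in set 4. Chance gives such a value in about 1 in 20 groups.

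Levels that stood apart in endoderm with mesoderm were those of sgk1 in set 4 (8.82 on the log2 scale, others 6.93 to 7.07), sox9 in set 3 (8.18, others 9.16 to 9.35), hey1 in set 4 (7.44, others 8.91 to 9.14), sox17a in set 4 (6.89, others 9 to 9.41) and cdx2 in set 3 (7.7, others 6.52 to 6.67). In endoderm alone they were foxa4 in set 4 (7.07, others 7.90 to 8.06), pitx1 in set 3 (8.27, others 10.2 to 10.3) and nr1h5 in set 1 (6, others 4.37 to 4.41). Log2 differences that stood apart were those of slc16a6 in set 3 (-1.04, others -1.82 to -1.70), cebpa in set 3 (1.6, others -0.14 to 0.06), irx3 in set 4 (2.26, others -0.48 to -0.15) and sox17a in set 4 (-1.50, others -0.33 to -0.10). List medians that stood apart were those of the apoptosis list in set 4 (-0.202), the cell cycle list in set 1 (0.0559) and the ribosomal protein list in set 4 (-0.266, others 0.0859 to 0.112).

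The lists of blood and vascular, cardiac and lateral plate, and posterior endoderm genes, most of them dim, were higher in camera at its preset correlation chiefly in set 4, where the 50 negative control probe sets also stood 0.36 higher and the actin 3' minus 5' log2 value went from -1.32 alone to 1.00, while that of GAPDH went from 3.26 to 3.31. A raised background on the array with mesoderm of that set may be their cause: within sets, their adjusted p without set 4 were 0.417, 0.86 and 0.417. For the BMP response list the same test, at the preset correlation, gave 0.00177, with medians above 0 in sets 1 to 3. Background, or another difference of set 4 alone, would not raise the medians of sets 1 to 3. The p itself decides nothing, since no estimated correlation was run without set 4. With all sets and an estimated correlation the adjusted p of this list was 0.374, and those of the other 3 lists 0.692. A difference in RNA quality or labelling in set 4 stays open for the other 3 lists. RNA of other tissues left on the endoderm, and an effect of mesoderm during culture, stay open for all 4 lists, the latter untested beyond the comparison itself.

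Without the set block the real split gave 0 probe sets, so the splits of the 8 arrays into 4 and 4 say nothing about chance for that count: all 35 give at least 0. The highest of the others, 283, came from the split of sets 1 and 2 against sets 3 and 4, which points to a structure of the sets, and the set-blocked count was 60. For lists, 15 of 35 splits gave at least the 4 of the real split, with 9 as the highest other, so chance cannot be excluded; most of these splits, unlike the real one, keep the 2 arrays of some sets together. Within sets there are 8 ways to swap the labels, too few for a share under 0.05. The real labels gave 60 probe sets and the highest other 0, so 1 of the 8 gave as many; for lists 6 of the 8 gave at least the real 4, with 8 as the highest other.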

How the results depend on the processing

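The alternatives within sets, cyclic loess and leaving out sets in the list tests were chosen after the result was seen, and the others were planned. Of the values of named genes under alternatives, 835 kept their direction and side of the threshold, 65 came to pass, most of them with the set block, and 88 were of uncalled genes whose sign turned. The fit without the set block called no named gene, so these counts hold no lost call. Of 24 named genes called within sets, 10 passed after cyclic loess and 14 did not, with the same direction in each. Of the values of single lists, 494 kept both, 38 came to pass, 48 lost their call and 50 uncalled ones turned sign. No called list was called in the other direction under an alternative. For named genes these counts could not show such a reversal, since none was called without the block.

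Without the set block, where 0 probe sets were called higher and 0 lower by limma (203 and 181 at an unadjusted p under 0.05), the block gave 40 and 20, the block as a random effect 56 and 26, and non-overlap of the groups 160 and 133. The 1 probe set lower in the brightest 3873 probe sets, with 1 mean per gene, and without the array with mesoderm of set 4 or all of set 4 was that of sgk1. Leaving out single arrays or sets gave 0 to 1 lower. Within sets, against 40 higher and 20 lower, array weights gave 220 and 210, quantile normalization 15 and 10, cyclic loess 13 and 8 (all 21 among the 60), probe sets above the median level 2 and 5, the brightest 3873 2 and 3, and 1 mean per gene 14 and 9. An adjusted p under 0.01 left 0 and 1 (sgk1), one under 0.10 gave 62 and 44, and a fold of at least 2 left 12 lower. Both filters kept sgk1, ambp, mt4 and szl. Without 1 set the counts ran from 0 (without set 2) to 168 (without set 4) higher and 0 to 107 lower. Except where a stricter threshold made the count, the cause was not tested. The filters left dim called probe sets out, but sox9, sesn1 and pdk4, which lie above the median level, also lost their call.

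Against 4 lists higher and 0 lower without the block, an estimated correlation gave 0 higher, fry 0, the mean of the probe sets of a gene 7 higher and 1 lower, genes above the median level 1, quantile normalization 2 and cyclic loess 2. Leaving out single arrays or sets gave 0 to 9 higher and 0 to 2 lower (2 without the array with mesoderm of set 2; 1 without the array alone of set 1, that of set 4, or set 1). Within sets, against the same counts, an estimated correlation gave 0, fry 0, genes above the median level 1, quantile normalization 1 and cyclic loess 1, and the mean of probe sets gave 1 lower. Without 1 set, 2 (without set 4) to 9 (without set 3) were higher and 0 to 1 lower (1 without set 1). Over all alternatives the adjusted p of the BMP response list ran from 4.5e-06 to 0.868, that of the blood and vascular list from 0.000122 to 0.823, that of the cardiac list from 0.00257 to 0.823 and that of the posterior list from 0.00379 to 0.823, and within sets the highest were 0.374, 0.692, 0.86 and 0.692; the cause was not tested.

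The first component held 39.0% of the variance and 52.4% after set means were removed, when the arrays with mesoderm of 3 of the 4 sets lay on one side. The planned series matrix table was identical to the other and changed nothing. Signal over background limits the dim genes, such as hhex and, in sets 2 to 4, nr1h5, which lay close to the negative controls.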

Other observations

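In this part the lists of myeloid genes and of FoxO and glucocorticoid receptor targets were written after the called genes were seen, as were the tests on the myeloid list; the test of the FoxO list had not been seen when its bounds were set. Within sets, 17 of 17 measured genes known from myeloid cells, of 50 written down, stood higher with mesoderm, with a median log2 difference of 0.57. The medians in sets 1 to 4 were 0.394, 0.921, 0.709 and 0.558. The list was written from the called genes and holds 5 of them, so its median is no independent evidence: prtn3, lcp1, fcrg, csf2rb and pik3r5 (0.86 ± 0.10), a regulatory subunit of a kinase of white blood cells. Not called were the lysosomal protease gene ctss (1.59 ± 1.27), cd37, a surface protein of leukocytes (0.90 ± 0.33), and hck, a kinase of myeloid cells (0.57 ± 0.39).

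Among targets of FoxO factors and the glucocorticoid receptor, 9 of the 13 members not called stood below 0 and 4 above. G6pc1, which releases glucose from its phosphate, stood at -0.93 ± 0.77, with 0.09 in set 2 and -1.75 in set 4, the glucocorticoid target tsc22d3 at -0.68 ± 0.37 and the catalase gene cat at -0.47 ± 0.34. Irs2 stood at -0.33 ± 0.35, igfbp1 at -0.29 ± 0.37, glul, the brightest, at -0.23 ± 0.17, pck1 at -0.22 ± 0.12, per1 at -0.18 ± 0.10 and klf9 at -0.00148 ± 0.29. Above 0 were the insulin receptor gene insr at 0.25 ± 0.40, the superoxide dismutase gene sod2 at 0.09 ± 0.18, cited2 at 0.07 ± 0.12 and gabarapl1 at 0.07 ± 0.33.

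The rise of myeloid genes may come from RNA of myeloid cells in the dissected endoderm. The 12 members not called, of which mpo and cebpa had been seen in the blood and vascular list (2 genes shared with it), stood above 0 with a median of 0.286 and a camera p of 3.05e-06 (0.0161 with an estimated correlation), but the abundant genes cxcr4 and cebpa differed by 0.03 and 0.37 and mpo by 2.08. The medians of the 12 in sets 1 to 4 were 0.13, 0.346, 0.153 and 0.421. They were highest in sets 4 and 2, like those of the negative controls. A raised background on the array of set 4 alone would not raise the medians of the other sets, which also lay above 0. Without set 4 the camera p of the 12, at the preset correlation, was 2.02e-05. It was 0.000762 for the 10 without mpo and cebpa, and 4.98e-13 with the called members, which were picked for their rise. These p decide nothing about background. The list was written after the called genes were seen, and no estimated correlation was run without set 4. Carry-over of the whole mesoderm layer cannot be told apart, since the cardiac and lateral plate list had a p of 0.738 without set 4 and no array of mesoderm shows what level a given share would bring. Expression of these genes in the endoderm itself under the influence of mesoderm stays open and untested; the labels name no sort that would remove blood cells.

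The genes lower with mesoderm include known targets of FoxO factors and of the glucocorticoid receptor, and 13 of 17 measured members of such a list (33 written; 1 shared with the stress list and 1 with the apoptosis list) lay below 0, with a median of -0.285. The list holds 4 genes whose fall prompted it, among them mt4, whose identity stays in doubt. That these targets fell as a group was tested on the 13 members not called. Their median was -0.222, with 9 below 0 and a camera p of 0.00283, but the p was 0.139 with an estimated correlation and the median was 0.0202 in set 2, so a common fall cannot be told apart from changes of the 4 called genes alone. A difference in handling, since endoderm alone was isolated at the start of culture and the other at its end, is tied to the 2 conditions and was not tested.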
